A study of Mus musculus with 49 samples.

How the data were processed

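Expression was measured in PBMC of mice given oleic acid (OA) or physiological serum, with 1 filter per array and 1 radioactive label. Per the labels' protocols, the total RNA was isolated with a kit for mouse blood and amplified linearly as antisense RNA before labelling. The extraction text speaks of lung whereas the source and tissue labels of the same samples give PBMC, and the latter is used here. Whether mononuclear cells were isolated or whole blood was used is not settled. Group, time, mouse number and array number were taken from the labels. The series text counts 1 more serum mouse at 1.5 h and 1 more OA mouse at 3 h, which were not analysed here.

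The array files deposited by the authors hold 1 integrated spot intensity per spot on a linear scale, as whole numbers from 15 to a shared ceiling of 21815, with no separate background column. They also hold a deposited quality score per spot of 0 or 1, which was not used as a filter. The header of these files names 5 of their 6 columns, and the signal column was found from its values. The image quantification settings are not given in the sources used here. The authors also deposited a table of log2 values that were quantile normalized over all 49 arrays without adjustment on serum, per the file headers, and a table of log2 values per array. Set against the former, the latter holds for serum arrays the same values, and for OA arrays the ratio to the mean serum array of the same time. This held within 0.005 for 48 arrays. The array numbered 38, titled OA 3 h mouse 3, matched serum of 1.5 h within 0.005 and differed from serum of 3 h by up to 3.74. It was kept at 3 h, as titled. The median of the quantile table is 7.4.

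Here, the analysis started from the spot intensities. On each array 2213 empty, control and other non-clone spots were left out (1478 empty spots, 192 named CG03 and 512 named na among them), and 7771 clone spots remained. Intensities were not background corrected, since no background is given, and were log2 transformed and quantile normalized between arrays. Spots of the same clone were averaged, which gave 7739 clones, and the 2 arrays of a mouse were averaged before any test. Gene names come from the files and were updated through the reference gene table (assembly GRCm38.p6), by current symbol for 6430 clones and by synonym for 1045. In all, 7475 clones had a gene symbol and represent 5776 genes, and 264 kept the file's name or none. A gene with several clones is represented by the clone with the highest mean signal over all mice.

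A clone was taken as well above background on an array when its signal exceeded the median of that array's empty spots by 2.6 robust SDs. This rule was set after the data were seen and replaced a stricter one, the 95th percentile of the empty spots. It affects only the wording of levels and bounds, not the tests. Where no array of a group measured a clone, the fold is a bound, the bright group's mean against the mean over arrays of the higher of the lowest signal well above background and the clone's own. On the arrays, 10 to 26 spots were at the ceiling, and 8 clones were at the ceiling on every array. Arrays of the same mouse correlated with a median r of 0.553 across clones, after removal of the mean of each clone, against 0.247 for mice of the same group and -0.0581 for mice of different groups. The ranges overlapped, with 0.2293 to 0.7997 within a mouse and up to 0.8023 between mice of different groups. Of the 24 arrays of mice with 2 arrays, 12 had the other array of the same mouse as their closest. The median absolute log2 difference was 0.2266 within a mouse and 0.2904 between mice of 1 group.

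Tests used limma 3.58.1 in R 4.3.3, with lmFit, contrasts.fit and eBayes on 1 value per mouse, a mean for each of the 12 groups and 1 shared estimate of the spread, which the serum groups of 1 or 2 mice need. The p-values were adjusted with the Benjamini-Hochberg method over clones, at a threshold of 0.05. Comparisons were OA against serum averaged over the 6 times and at each time, late (18 and 24 h) against early (1 and 1.5 h) within OA and within serum mice with both times weighted equally, the difference between these, and an F test of whether the OA effect differs among times. On simulated arrays with 200 of 7739 clones changed, the code recovered 94.7% of 2-fold and 99.9% of 4-fold changes averaged over times, 46.8% and 89.8% at 4 h, and 87% and 99.3% for late against early OA mice, over 10 simulations. Median false calls were 3, 2 and 2, with at most 24, 649 and 11. The changes were given to all OA mice at all 6 times, to the OA mice at 4 h, or to the late OA mice.

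Fixed before the data were examined were the groups, tests, alternatives, 21 gene lists and the rule for named genes. The lists cover inflammatory cytokines and NF-kB targets, immediate-early and stress response, glucocorticoid-responsive and interferon-stimulated genes, markers of neutrophils, monocytes and macrophages, T cells, B cells, NK and cytotoxic cells, erythroid cells, platelets and megakaryocytes, and lung epithelium and endothelium, MHC class II presentation, cell cycle, fatty acid oxidation and PPAR targets, oxidative stress and metallothioneins, apoptosis, hypoxia and glycolysis, heat shock and chaperones, ribosomal proteins and oxidative phosphorylation. They were tested with camera at a correlation of 0.01 and again with an estimated correlation, under which 0 lists were called, with 3 tests of OA against serum and 3 of late against early at an unadjusted p under 0.05. Tests of the lists for late against early were added after the data were seen.

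The genes named are the 10 largest rises and 10 largest falls past the threshold for the averaged comparison and late against early OA mice, 5 and 5 for the others, and the 5 smallest p for the F test. Where fewer passed, all that passed are named and the smallest p fill up to 5, given as not past. Up to 4 members of each list with the smallest p could be named, for the average or where the list was called. Il1b, Tnf, Il6, Il1rn, S100a8, S100a9, Lcn2, Cd14, Cd3e, Cd79a, Hba-a1, Fos, Nfkbia, Tsc22d3, Ucp2 and Cpt1a were to be given where measured, and Tnf, Il6, Cd79a, Tsc22d3 and Ucp2 were not among the named clones. Examples from lists in late against early OA mice follow the same order of p, a choice made after the data were seen. A few genes that these rules take are not reported here.

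Alternatives set beforehand were scaling to the median, normexp background correction (offset 50, with the background taken from the empty spots, where the lowest signals of each array had been foreseen), both deposited tables (OA values of the ratio table rebuilt by adding back the serum mean of the titled time), leaving out the dimmest 25% of clones, 1 array per mouse, the array number as a covariate, fitting only the compared groups, the average without 1.5 h, a block on mouse number, and leaving out each mouse in turn. Alternatives chosen after seeing the data were the score on the first principal component as a covariate, leaving out the 7 mice that stand apart on it, array 38 as a mouse of 1.5 h, late against early without each of its 4 times in turn, with a count from the reported changes at the SE of each such fit, the ratio table with 1.5 h serum added back to array 38, and the lists for OA against serum without the 7 mice.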

Results

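Peripheral blood mononuclear cells (PBMC) were profiled in female wild-type C57Bl/6J mice after an injection into the tail vein of oleic acid (OA), a fatty acid that injures the lung when given this way, or of physiological serum as the control. Blood was taken at 1, 1.5, 3, 4, 18 and 24 h. Each RNA was amplified and hybridized, with a radioactive label, to nylon filters carrying spotted mouse cDNA. The data comprise 49 arrays of 37 mice, of which 26 received OA (n = 4, 6, 4, 4, 4 and 4 in order of time) and 11 received serum (n = 2, 1, 2, 2, 2 and 2). For 12 mice the RNA was hybridized to 2 filters, and these were averaged to 1 value per mouse. The median clone signal ranged from 83 to 364 between arrays, and 41.8% to 57.88% of clone spots on an array were well above the empty spots. Values are log2 normalized signals with the SD over mice, and changes are log2 differences with their standard error (SE). The number of arrays limits the precision. At most times 4 OA mice were set against 2 serum mice, which gave a median SE of 0.287.

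The series asks whether expression in PBMC follows the stages of inflammation after the injury. The time course in OA mice describes change over time, and the serum mice and the comparisons at matched times are needed to say what belongs to the injury. In OA mice Il1b, Junb and Lmnb1 fell from early (1 and 1.5 h, n = 10) to late (18 and 24 h, n = 8), and Mpp1 and Alas2 rose. Il1b, which encodes the inflammatory cytokine interleukin-1 beta, fell 5.48-fold, from 12.57 ± 1.38 (SD, n = 10) to 10.01 ± 1.69 (n = 8), a log2 change of -2.45 (SE 0.54, adjusted p = 0.00661). Junb, an immediate-early transcription factor, fell 5.33-fold (13.36 ± 0.93 to 10.91 ± 0.68, adjusted p = 0.0039), and Lmnb1, which encodes lamin B1 of the nuclear envelope, fell 5.36-fold (11.68 ± 1.18 to 9.15 ± 0.53, adjusted p = 0.00296). Mpp1, a membrane protein abundant in red cells, rose 3.18-fold (well above background on 7 of 13 early arrays, 7.46 ± 0.49 to 9.12 ± 1.22, adjusted p = 0.00155), and Alas2, the erythroid enzyme that starts heme synthesis, rose 2.69-fold (12.29 ± 1.19 to 13.69 ± 0.68, adjusted p = 0.0298). In each of these 5 genes all 8 late mice lay on the same side of the early mean, although the genes were chosen by their change in these mice. The changes at 24 h alone were -3.71 (SE 0.67) for Il1b, -2.49 for Junb, -2.63 for Lmnb1, 2.6 for Mpp1 and 1.91 for Alas2. At 18 h alone they were -1.2 (SE 0.67), -2.34, -2.22, 0.74 and 0.95. Without 1.5 h they were -1.89, -2.22, -1.92, 1.72 and 1.57. With these fewer mice none of the 5 passed without 24 h (adjusted p from 0.1 to 0.495) or without 1.5 h (0.0543 to 0.217), and Alas2 did not pass without 1 h (1.29, adjusted p = 0.0755).

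Of 7739 clones, 637 changed between early and late OA mice, 337 of them up and 300 down. The other large falls were those of Clec4d, a lectin receptor of myeloid cells (3.4-fold, well above background on 6 of 11 late arrays), Csrnp1 (3.37-fold), G0s2, an inhibitor of lipolysis (3.02-fold, on 3 of 11), Cirbp, the cold-inducible RNA-binding protein (2.97-fold), Il1rn, which encodes the interleukin-1 receptor antagonist (2.83-fold), the chromatin remodeller Chd4 (2.78-fold) and the protease inhibitor Slpi (2.72-fold). Their adjusted p-values lay between 0.00262 and 0.025, and all 8 late mice were below the early mean for each. Among the largest rises were Cmas, which activates sialic acid (3.23-fold, adjusted p = 0.00155), Hagh, a glyoxalase (3-fold), Glrx5, a mitochondrial glutaredoxin needed for iron-sulfur clusters (2.98-fold), glutathione peroxidase Gpx1 (2.9-fold), Ghitm (2.71-fold), Isg20 (2.7-fold) and Aldh1a1 (2.69-fold). At least 7 of the 8 late mice were above the early mean for each of them. Gpx1 was at the signal ceiling on 7 arrays, and Hagh was well above background on 10 of 13 early arrays. The count varied with the times and mice compared: without 1.5 h it was 0 (1090 clones at an unadjusted p under 0.05), without 24 h 4, without 18 h 1274 and without 1 h 725, where Isg20 did not pass (adjusted p = 0.0534). Without 1.5 h the median change of the 637 clones was 0.91 times its size and the SE 1.28 times, and the reported changes at that SE would also give 0. Without 24 h the change was 0.69 times and the SE 1.24 times, and the reported changes at that SE would give 35. Of 65 named genes, 60 kept at least 0.75 of their change without 1.5 h, and 19 without 24 h. At 18 h alone 629 of the 637 clones had the same sign, and at 24 h alone all 637, at 1.27 times the median change. The clones and named genes were selected by their change in these same mice. These shares, and the numbers of late mice on 1 side of the early mean, are therefore not independent support. Scaling each array to its median in place of quantile normalization gave 852 clones, 560 up and 292 down. With that scaling Hba-a1, at the ceiling on all 49 arrays, gave 0.63 (limma adjusted p = 0.00988). A saturated clone cannot show a rise, so this value comes from the lower medians of the late arrays. Leaving out OA 1 h mouse 5 gave 256 clones, OA 1 h mouse 6 330, OA 18 h mouse 5 371, OA 24 h mouse 2 340 and OA 24 h mouse 6 358, while leaving out the 7 mice that stood apart on the main axis of variation (1 of the 8 late and 0 of the 10 early OA mice) gave 1363.

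**Figure D1:**
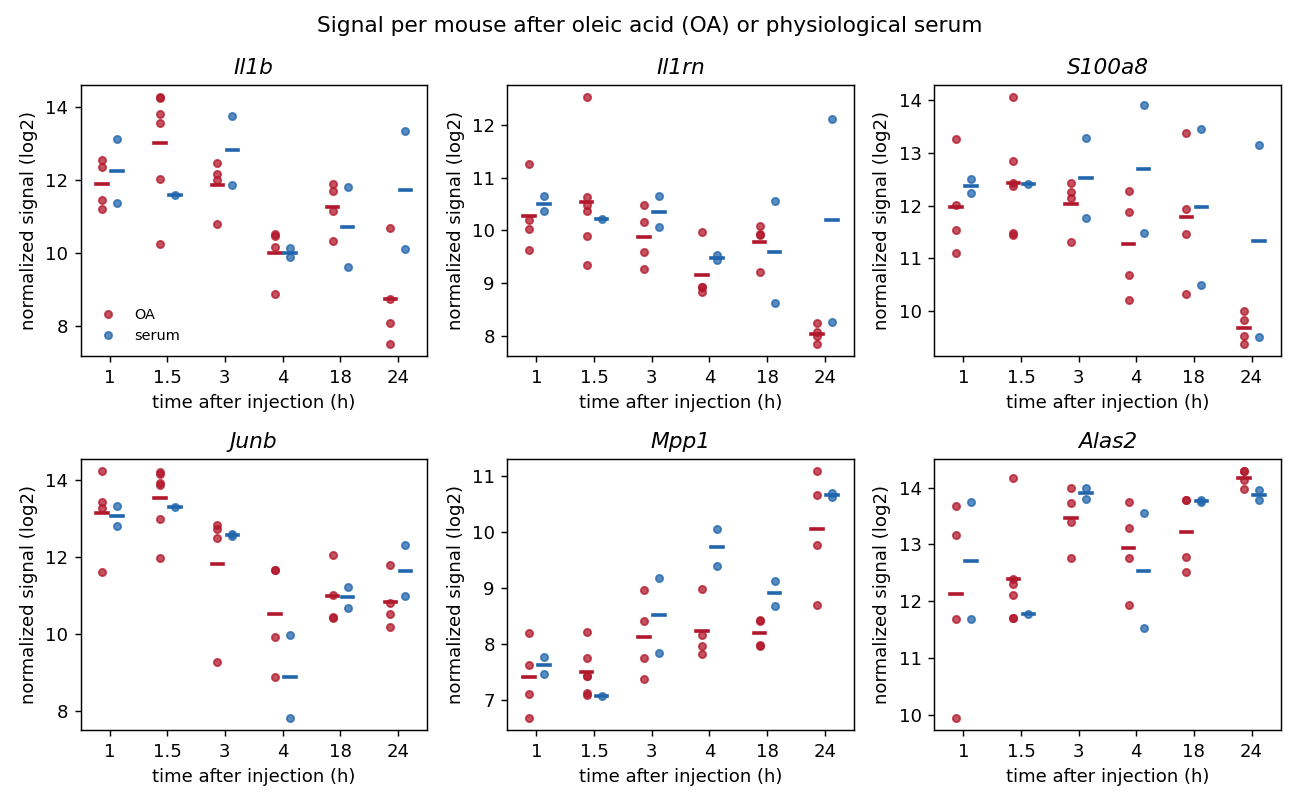
Normalized signal (log2, vertical axis) of 6 genes at each time after injection (hours, horizontal axis, evenly spaced) in mice given oleic acid (OA, red) or serum (blue). Each point is 1 mouse and each bar the group mean. Il1b and Junb lie lower and Mpp1 and Alas2 higher at 18 and 24 h than at 1 and 1.5 h in OA mice, and the 2 serum mice at 24 h lie far apart for Il1b, Il1rn and S100a8.

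Among inflammatory cytokines and NF-kB targets, 3 of 27 measured genes fell from early to late in OA mice and 0 rose (adjusted over the list alone, 6 fell and 1 rose). These were Il1b, Il1rn and the chemokine Ccl6 (log2 change -0.9, SE 0.24). The list as a whole was lower late (adjusted p = 0.0281), which did not hold with an estimated correlation between genes (adjusted p = 0.669), without 24 h (adjusted p = 0.391) or without 1.5 h (adjusted p = 0.516). In the immediate-early and stress list 3 of 19 genes fell, Junb, Gadd45b (-1.4, SE 0.31) and Fosl2 (-1.32, SE 0.37), and 5 fell and 1 rose when adjusted over the list alone (list adjusted p = 0.27). Fos gave -0.42 (SE 0.42, adjusted p = 0.55) and the NF-kB inhibitor Nfkbia -0.66 (SE 0.29, adjusted p = 0.142). Of 17 neutrophil markers, 3 fell (5 when adjusted over the list alone), namely the granule protein gene Ltf (-0.9, SE 0.17), Clec4d and the decoy receptor gene Il1r2 (-0.96, SE 0.23), and the list had an adjusted p of 0.0538 (0.669 with an estimated correlation, 0.00928 without 18 h and 0.6 without 24 h, 0.00472 without 1 h and 0.445 without 1.5 h, 0.027 with median scaling). The calprotectin genes S100a8 (-1.48, SE 0.5, adjusted p = 0.0653) and S100a9 (-1.19, SE 0.48, adjusted p = 0.111) and Lcn2 (-0.55, SE 0.36, adjusted p = 0.346) did not pass. In the glucocorticoid-responsive list 2 of 13 genes fell, Il1r2 and the kinase gene Sgk1 (-0.89, SE 0.26), 4 when adjusted over the list alone (list adjusted p = 0.36). None of the genes in this paragraph passed over all genes without 24 h or without 1.5 h, with fewer mice in each. Without 24 h the changes were about as large in Ltf (-0.93), Il1r2 (-0.87) and Gadd45b (-1.22) and smaller in Ccl6 (-0.37) and Sgk1 (-0.5). Without 1.5 h they were about as large in Il1r2 (-1.07) and Ltf (-0.8) and smaller in Ccl6 (-0.52) and Gadd45b (-0.87). S100a8 (-2.52, adjusted p = 0.00774) and S100a9 (-2.1, adjusted p = 0.017) passed without 18 h, and S100a9 (adjusted p = 0.0417) and Nfkbia (-1.13, adjusted p = 0.0289) passed without 1 h. Their changes were small in the opposite fits. Without 24 h S100a8 gave -0.43 (SE 0.63) and S100a9 -0.27 (SE 0.59), and without 1.5 h S100a9 gave -0.65 (SE 0.61) and Nfkbia -0.18 (SE 0.37).

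Erythroid markers lay higher as a list in OA mice at 24 h. With both late times (18 and 24 h), 19 of 20 measured genes had a positive change and 4 rose (7 when adjusted over the list alone). These were Alas2, Trim10 (0.78, SE 0.2), the Rh antigen gene Rhd (0.69, SE 0.14) and carbonic anhydrase gene Car1 (0.57, SE 0.13). At 24 h alone Alas2 gave 1.91, Trim10 1.67, Rhd 1.3 and Car1 0.95, and at 18 h alone 0.95, -0.12, 0.09 and 0.18. Rhd and Car1 were not well above background in early mice, so no fold is given. The list was higher late (adjusted p = 0.000173), but not with an estimated correlation (adjusted p = 0.531). Its adjusted p was 5.11e-07 at 24 h alone and 0.65 at 18 h alone, where the mean deviations of the 4 mice (-0.372 to 0.234) lay within those of the early mice (-0.702 to 0.238). The alpha-globin gene Hba-a1 was saturated on all 49 arrays, so the level of globin RNA could not be compared. In the list of oxidative stress genes and metallothioneins 5 of 31 genes rose (6 when adjusted over the list alone), among them Gclm, a subunit of the enzyme that limits glutathione synthesis (1.38, SE 0.3), Prdx2, an abundant red cell peroxiredoxin (1.3, SE 0.36), catalase, Cat (1.14, SE 0.33), and Nfe2l2 (0.65, SE 0.17), with a list adjusted p of 0.293. Ribosomal protein genes moved the other way. Of 48 genes 3 had a positive change and 4 fell (9 when adjusted over the list alone), among them Rps16 (-0.86, SE 0.14, at the ceiling on 3 arrays), Fau (-0.97, SE 0.27) and Rpl28 (-0.54, SE 0.15). The adjusted p of this list was 2.94e-07, and 0.531 as an adjusted p with an estimated correlation. It was 1.84e-09 at 24 h alone and 0.151 at 18 h alone (unadjusted p = 0.00718). In oxidative phosphorylation 4 of 61 genes rose (4 when adjusted over the list alone), for example the complex I subunit Ndufs3 (1.23, SE 0.22, the other clone of which had the opposite sign) and Cox7b (1.02, SE 0.26), and the list did not move (median -0.05, mean 0.04, adjusted p = 0.973). None of the genes in this paragraph passed without 24 h, where Trim10 had the opposite sign (-0.12, SE 0.25), Rhd gave 0.09 and Prdx2 0.2, but Cox7b 1.02. None passed without 1.5 h either, although the changes were about as large, as in Gclm (1.43), Prdx2 (1.4), Ndufs3 (1.29), Cox7b (1.03) and Rhd (0.67). Alas2 and Prdx2 (adjusted p = 0.059) did not pass without 1 h.

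Among T cell markers 4 of 32 genes fell and 2 rose (5 and 3 when adjusted over the list alone), with falls that included Tox (-0.52, SE 0.13), Ctla4 (-0.67, SE 0.18) and Cd2 (-0.38, SE 0.1), and the list had an adjusted p of 0.27. Cd3e gave -0.94 (SE 0.32, adjusted p = 0.0659), with the opposite sign in its other clone. Of 22 B cell markers, Cd37 (-0.72, SE 0.15) and Cd83 (-0.64, SE 0.14) fell and Cd24a (1.09, SE 0.32), which is also present on red cells and their precursors, rose (3 fell and 1 rose when adjusted over the list alone, list adjusted p = 0.779). The monocyte and macrophage list had 1 rise among 27 genes (1 when adjusted over the list alone), the cathepsin gene Ctsb (0.92, SE 0.24), and an adjusted p of 0.819. Cd14 was not well above background in either group. In 16 NK and cytotoxic markers limma called 0 genes over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 (list adjusted p = 0.779). Of 29 interferon-stimulated genes 3 rose (3 rose and 1 fell when adjusted over the list alone), among them Isg20 and Ifi44 (0.86, SE 0.25), with a list adjusted p of 0.973. The integrin gene Itga2b was the only platelet marker past the threshold among 12, with a fall of -0.74 (SE 0.19; 1 when adjusted over the list alone; list adjusted p = 0.509). In MHC class II presentation the invariant chain gene Cd74 fell (-0.9, SE 0.26) and Cd86 rose (0.4, SE 0.11) among 10 genes (the same numbers when adjusted over the list alone, list adjusted p = 0.519). None of the genes in this paragraph passed over all genes without 24 h, where the change was about as large in Ctla4 (-0.65) and Cd37 (-0.65) and smaller in Ctsb (0.23) and Isg20 (0.41). None passed without 1.5 h, where changes such as those of Cd37 (-0.71), Tox (-0.55) and Ctsb (1) were about as large, nor did Isg20 (adjusted p = 0.0534), Ifi44 (0.0588) and Itga2b (0.122) without 1 h.

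Of 56 cell cycle genes, 4 rose and 0 fell in late OA mice (6 and 0 when adjusted over the list alone, list adjusted p = 0.735), including the spindle gene Nusap1 (1.04, SE 0.25), cyclin gene Ccne1 (0.7, SE 0.18) and Cdk2 (0.72, SE 0.21). In fatty acid oxidation and PPAR targets 1 of 30 genes rose and 1 fell (1 and 3 when adjusted over the list alone, list adjusted p = 0.735). Acsl1, which activates long-chain fatty acids, rose (0.81, SE 0.18), and the thioesterase gene Acot2 fell (-0.47, SE 0.11). Cpt1a gave 0.23 (SE 0.09, adjusted p = 0.101) and was not well above background early. Apoptosis genes showed 3 rises among 28 (3 when adjusted over the list alone, list adjusted p = 0.847, test direction up with a median of -0.08 and a mean of -0.01), the caspase gene Casp12 (0.5, SE 0.14), Bcl2l1 (0.56, SE 0.17) and Cflar (0.51, SE 0.15). The chaperone Cct5 rose (0.42, SE 0.12) as the single gene of 28 in the heat shock list (0 when adjusted over the list alone, list adjusted p = 0.779, median 0.01, mean -0.05), and endoglin, Eng, fell (-0.99, SE 0.2, with the opposite sign in its other clone) as the single gene of 20 lung epithelium and endothelium markers (1 when adjusted over the list alone, list adjusted p = 0.519). In hypoxia and glycolysis limma called 0 of 21 genes over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05 (list adjusted p = 0.27). The examples from these lists were taken by smallest p. None of them passed over all genes without 24 h, where the change was about as large in Eng (-1.18) and Cct5 (0.45) and smaller in Ccne1 (0.04) and Acsl1 (0.28). None passed without 1.5 h, where changes such as those of Ccne1 (0.92), Acsl1 (0.78) and Eng (-1.12) were about as large, nor did Ccne1 without 1 h (adjusted p = 0.122) and Cct5 without 18 h (0.0824). Cpt1a passed without 18 h (0.43, adjusted p = 0.0105) and gave 0.04 (SE 0.11) without 24 h.

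The serum mice show how far the same interval alters blood expression without OA. Mpp1 rose 5.42-fold from early (7.43 ± 0.35, n = 3) to late (9.78 ± 1.03, n = 4) in serum mice, a log2 change of 2.44 (SE 0.46, adjusted p = 0.0451). Ltf fell at least 1.98-fold, because the late serum mice were not well above background (log2 change -1.54, SE 0.28, adjusted p = 0.0451). In both genes all 4 late mice lay on one side of the early mean. These were the 2 clones past the threshold, followed by Morc3 (0.93, SE 0.22, adjusted p = 0.4), Aqp11 (-0.6, SE 0.14, adjusted p = 0.4, not well above background late, with 1 early mouse at 7.94) and Usp3 (-0.71, SE 0.2, adjusted p = 0.49). Erythroid markers were higher late (18 of 20 genes positive, adjusted p = 0.00675, but adjusted p = 0.669 with an estimated correlation), and ribosomal protein genes lower (adjusted p = 1.61e-06, but adjusted p = 0.531 with an estimated correlation). At 24 h alone their adjusted p-values were 7.52e-05 and 7.47e-09, and at 18 h alone 0.526 and 0.114 (unadjusted 0.189 and 0.00272). NK and cytotoxic markers were not called (adjusted p = 0.27, and 0.669 with an estimated correlation), except without 1 h (0.0475, against 0.391 to 0.874 without another time). In these lists limma called 0 genes over all genes or adjusted over the list alone, with 2 erythroid and 7 ribosomal genes at an unadjusted p under 0.05. Alas2 gave 1.56 (SE 0.68, adjusted p = 0.532) and Rps16 -0.74 (SE 0.24, adjusted p = 0.49). Across all 7739 clones the late minus early changes in OA and in serum mice, which share no animals, had a Pearson correlation of 0.721 (Spearman 0.684), a correlation across clones, which are not independent replicates. Of the 637 clones called in OA mice, 614 had the same sign in serum mice, with a median change of 0.64 in OA and 0.46 in serum mice. For Il1b the change in serum mice was -0.69 (SE 0.89, adjusted p = 0.845), and its difference from that in OA mice was -1.76 (SE 1.04, adjusted p = 1). Neither of the 2 calls was made when any 1 of serum 1 h mouse 1, 18 h mouse 1 or 24 h mouse 1 (0 clones each), or of serum 1 h mouse 4 or 18 h mouse 4 (1 other clone each) was left out. Without serum 24 h mouse 4 there were 6 clones, 1 of the 2 among them. Without 24 h or without 1.5 h limma called 0 clones, without 1 h 1 that was neither Mpp1 nor Ltf, and without 18 h 1, Mpp1. Over 16 alternatives Mpp1 and Ltf were called in 7 each.

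**Figure D2:**
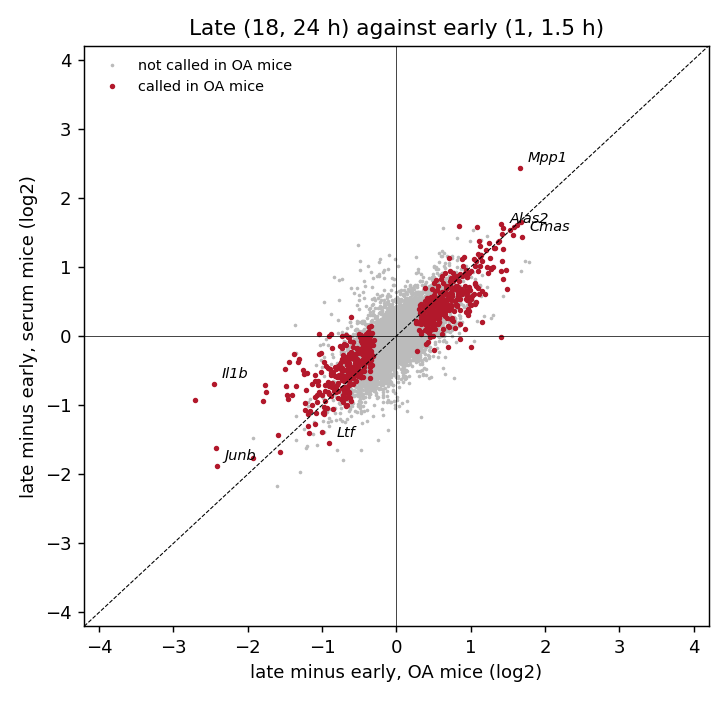
Late (18 and 24 h) minus early (1 and 1.5 h) log2 change per clone in OA mice (horizontal axis) against serum mice (vertical axis), with each point 1 clone, red where called in OA mice, and the dashed line marking equal change. Of the 637 red points, 614 have the same sign in both treatments.

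The comparison of OA with serum at matched times asks what the injury itself changes. Averaged over the 6 times, limma called 0 of 7739 clones, and 266 had an unadjusted p under 0.05, where 387 are expected with no effect. The smallest p-values belonged to the water channel gene Aqp11 (-0.26, SE 0.07), the phosphatase inhibitor gene Ppp1r1b (-0.31, SE 0.08) and Hps4 (-0.38, SE 0.1), each with an adjusted p of 0.729, and to Haus2 (-0.37, SE 0.1) and Trim14 (-0.33, SE 0.09), each with an adjusted p of 1. Hps4 was higher in OA than in serum mice at 3 h (8.07 ± 0.11, n = 4, against 7.79 ± 0.14, n = 2), and Aqp11 at 1 h (6.79 ± 0.17, n = 4, against 6.61 ± 0.05, n = 2) and 3 h (6.55 ± 0.15, n = 4, against 6.41 ± 0.05, n = 2). Il1b gave -0.38 (SE 0.42), Il1rn -0.45 (SE 0.31), S100a8 -0.69 (SE 0.39), S100a9 -0.38 (SE 0.37), Lcn2 -0.34 (SE 0.28), Fos -0.51 (SE 0.32), Nfkbia 0.22 (SE 0.22), Cd3e -0.05 (SE 0.25) and Cpt1a 0.12 (SE 0.07, not well above background in serum mice), all with an adjusted p of 1. Of the 21 gene lists, 0 were called by camera. Monocyte and macrophage markers came nearest, with 6 of 27 genes positive and a median of -0.09 (adjusted p = 0.0708), led by Tyrobp (-0.49, SE 0.27), Ccr2 (-0.41, SE 0.24) and Grn (-0.21, SE 0.12). Without the 7 mice apart and 4 h this list was called as lower (adjusted p = 0.0167), and at 1 h too (0.0447), but not with an estimated correlation (adjusted p = 0.963 without these mice and 0.992 with all). Neutrophil markers had 4 of 17 genes positive (adjusted p = 0.223). In these 2 lists limma called 0 genes over all genes or adjusted over the list alone, with 0 monocyte and 1 neutrophil gene at an unadjusted p under 0.05. The other 19 lists had adjusted p-values from 0.318 upward. Leaving out serum 3 h mouse 1 or serum 4 h mouse 1 gave 1 clone each, and serum 4 h mouse 4 or serum 18 h mouse 4 gave 2 each. On simulated data of this design, 94.7% of 2-fold changes were recovered for this average. There the change was the same in all OA mice at all 6 times. A change at 1 time only is diluted in the average, and for a change at 4 h the comparison at that time recovered 46.8% of 2-fold changes.

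**Figure D3:**
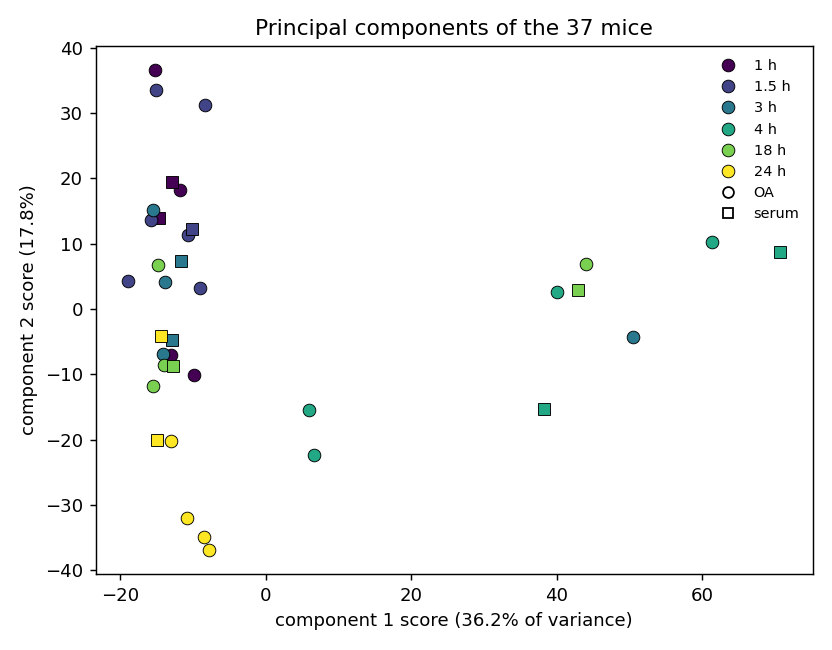
Scores of the 37 mice on the first (horizontal axis, 36.2% of the variance) and second (vertical axis, 17.8%) principal components of all clones, in arbitrary units. Each point is 1 mouse, colored by time, with circles for OA and squares for serum, and 7 mice, 4 given OA and 3 given serum, lie at 38.2 or more on the first axis.

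At 1.5 h, Aqp11 was at least 1.49-fold higher in the single serum mouse (7.94) than in OA mice (6.53 ± 0.12, n = 6, not well above background), with a log2 difference of -1.41 for OA against serum (SE 0.19, adjusted p = 0.000366, all 6 OA mice below). In every other group, OA or serum, Aqp11 had a mean of 6.28 to 6.8 and was well above background on 0 arrays, so this is a high value in 1 control and not a fall in OA mice. Inflammatory cytokines and NF-kB targets were higher in OA mice, with 21 of 27 genes positive and a median of 0.29 (adjusted p = 0.0165, but adjusted p = 0.992 with an estimated correlation), and limma called 0 of its genes over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. With median scaling this list was not called, whereas immediate-early genes (adjusted p = 0.00257), oxidative phosphorylation (0.00257) and ribosomal proteins (0.0207) were called as higher. Median scaling of all mice was not run with an estimated correlation. Without the 7 mice apart, median scaling with an estimated correlation called 0 lists. Among the members of the inflammatory list the smallest p-values are given next. They were those of Nfkbia (1.45, SE 0.65), Ccl5 (-1.09, SE 0.54) and the macrophage chemokines Ccl3 (1.13, SE 0.56) and Ccl4 (1.02, SE 0.55, not well above background in the serum mouse), each with an adjusted p of 1, and Il1b gave 1.44 (SE 1.22). Morc1 (-1.94, SE 0.41, adjusted p = 0.193), Umps, Nos3 and Adrm1 did not pass. Everything at this time rests on 1 serum mouse, whose spread is assumed to equal that of the other groups. The Aqp11 call was lost when the 1.5 h mice were fitted alone (adjusted p = 0.191) or the authors' deposited ratios were rebuilt with 3 h serum for array 38, as titled (adjusted p = 0.835), but kept when they were rebuilt with the 1.5 h serum they were made on (adjusted p = 0.00084).

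At 1 h and at 3 h limma called 0 clones, with 103 and 260 at an unadjusted p under 0.05. The smallest p-values at 1 h were those of the DNA methyltransferase gene Dnmt3b (-1.62, SE 0.32, adjusted p = 0.153, not well above background in OA mice), the B cell kinase gene Blk (-1.01, SE 0.33), Gpx3, Uri1 (-1.46, SE 0.5) and Mtmr4, the last 4 with an adjusted p of 1. At 3 h they were those of Rassf2 (-1.65, SE 0.45), Mcoln1, the B cell gene Fcrla (1.84, SE 0.52, a rise when adjusted over the list alone, 1 of 22 B cell genes), Orc6 (1.19, SE 0.34) and Gle1 (1.26, SE 0.37), each with an adjusted p of 1. MHC class II genes had 1 of 10 positive at 3 h (median -0.36, adjusted p = 0.0708). With median scaling this list was called as lower at 3 h (adjusted p = 0.0221), as were ribosomal proteins (0.00257) and interferon-stimulated genes (0.0448), and at 1 h monocyte and macrophage markers (0.0498). OA 3 h mouse 7 stood apart on the first component, with which MHC class II genes correlated at -0.86 and interferon-stimulated genes at -0.64 over mice. Without the 7 mice apart these 2 lists were not called at 3 h with median scaling (0.088 and 0.113), while ribosomal proteins (1.54e-05) were, oxidative phosphorylation as well (0.00444), and at 1 h monocyte markers (0.0122) and B cell markers (0.0287). With an estimated correlation 0 lists were called in these fits without the 7 mice. Leaving out serum 1 h mouse 1 or mouse 4 gave 1 and 2 clones at 1 h, and leaving out serum 3 h mouse 1 gave 4 at 3 h.

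At 4 h, 1 clone was higher and 3 lower in OA than in serum mice. Dld, a subunit shared by mitochondrial dehydrogenase complexes, was at least 1.18-fold higher (8.03 ± 0.32, n = 4, against 6.78 ± 0.31, n = 2, in serum mice, where it was not well above background; log2 difference 1.25, SE 0.24). Aldh9a1, an aldehyde dehydrogenase, was 2.03-fold lower (8.09 ± 0.22, n = 4, against 9.11 ± 0.24, n = 2; -1.02, SE 0.19). Ppp1r1b was lower too (-0.99, SE 0.18), with no fold because it was not well above background in OA mice. The adjusted p of these 3 genes was 0.0284. The fourth was a clone of Wrnip1, a partner of the Werner helicase, 3.24-fold lower (7.31 ± 0.47, n = 4, against 9.01 ± 0.6, n = 2; adjusted p = 0.000487; well above background on 2 of 5 and 2 of 3 arrays). It is not the brightest clone of its gene, so it falls outside the naming rule and was named after its value was seen. All 4 OA mice lay on the same side of the serum mean for each of the 4 clones. The thymidine kinase gene Tk1 (-0.94, SE 0.19, adjusted p = 0.0604) and the cathepsin gene Ctsz (1.76, SE 0.37, adjusted p = 0.0764) did not pass over all genes, and S100a8 gave -1.42 (SE 0.91, adjusted p = 0.506). Adjusted over the list alone, 2 of 56 cell cycle genes fell, Tk1 among them, 1 of 27 monocyte genes rose, Ctsz, and 1 of 20 lung genes rose and 1 fell. In all, 1006 clones had an unadjusted p under 0.05. Of the 7 mice that stood apart, 4 belong to this time, 2 OA mice and both serum mice. Leaving out serum 4 h mouse 4 gave 764 clones, OA 4 h mouse 2 19 and OA 4 h mouse 6 1, and fitting the 4 h mice alone ended all 4 calls (adjusted p = 0.782 for each). With 1 array per mouse none of the 4 passed. The differences of Wrnip1 (-0.73, SE 0.25, adjusted p = 0.282) and Ppp1r1b (-0.53, SE 0.18, adjusted p = 0.281) were then smaller. Over the alternatives run, the calls were kept in 6 of 10 for Dld, 4 of 10 for Aldh9a1, 4 of 9 for Ppp1r1b and 8 of 10 for Wrnip1.

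At 24 h the cyclin E1 gene Ccne1, which drives entry into DNA synthesis, was 3.52-fold higher in OA mice (10.11 ± 0.61, n = 4) than in serum mice (8.29 ± 0.07, n = 2), a log2 difference of 1.81 (SE 0.32, adjusted p = 0.0299), with all 4 OA mice above the serum mean. Il1b (8.75 ± 1.39 against 11.73 ± 2.29; -2.98, SE 0.97, adjusted p = 0.619), Il1rn (-2.16, SE 0.72, adjusted p = 0.619) and S100a8 (-1.64, SE 0.91, adjusted p = 0.746) did not pass over all genes. Between the 2 serum mice the SD of Il1rn was 2.73. Adjusted over the list alone, 3 of 27 inflammatory genes fell, including Il1b and Il1rn. Spcs3 (-0.68, SE 0.17), Asl, Drap1 and Trit1 did not pass either (adjusted p = 0.619), and 539 clones had an unadjusted p under 0.05. Interferon-stimulated genes had 5 of 29 positive at 24 h (median -0.29) and 21 of 29 positive at 18 h (median 0.15), each with an adjusted p of 0.0708. With median scaling this list was called at both times (0.0221 and 0.0207), and erythroid markers as higher at 24 h (0.0207). At 18 h 1 of 2 serum and 1 of 4 OA mice stood apart on the first component, with which the interferon list correlated at -0.64. Without the 7 mice apart and with median scaling it was called at 24 h (0.0194) but not at 18 h (0.953), where B cell markers were (0.0287), and erythroid markers were called at 24 h (0.0175). With an estimated correlation that fit called 0 lists, and median scaling of all mice was not run with one. At 18 h limma called 0 clones, with 95 at an unadjusted p under 0.05, and the smallest p-values included those of Ptgr1 (-0.94, SE 0.27), Pcsk5 (0.72, SE 0.21), Hps4 (-0.71, SE 0.23) and Timm50 (-0.6, SE 0.21), each with an adjusted p of 1. Leaving out OA 24 h mouse 2 or mouse 3 ended the Ccne1 call (0 clones), and leaving out serum 24 h mouse 4 gave 34 clones, 0 of them shared. Of 11 alternatives 6 kept the call, and it was lost with 1 array per mouse (1.6, adjusted p = 0.233), the array number as a covariate (1.76, 0.115), the 24 h mice alone (0.455) and without the 7 mice that stood apart (0.0894). It was lost with the ratio table when array 38 was rebuilt on 3 h serum (1.67, 0.0504), and kept on the 1.5 h serum of its ratios (1.67, 0.0407). At 18 h, leaving out serum mouse 1 or mouse 4 gave 1 and 4 clones.

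The last comparison asks whether the difference between OA and serum mice depends on time. Il1b (-1.76, SE 1.04), Il1rn (-1.03, SE 0.77) and S100a8 (-0.74, SE 0.97) had a late minus early difference in OA effect below 0 and none passed (adjusted p = 1). Limma called 0 clones, with 117 at an unadjusted p under 0.05. The smallest p-values were those of Sptlc1, which starts sphingolipid synthesis (-1.12, SE 0.34), Agfg2 (0.59, SE 0.18), the leukotriene receptor gene Cysltr1 (-0.6, SE 0.19), Metap1 (-1.39, SE 0.44) and AY074887 (1.51, SE 0.49), each with an adjusted p of 1. In the test over all 6 times limma again called 0 clones, with 252 at an unadjusted p under 0.05, and Aqp11 had the smallest adjusted p, 0.0782, followed by Spcs3 (0.673), Morc1 (0.95), Dld (1) and Ccne1 (1). In this test, leaving out serum 4 h mouse 4 gave 22 clones, serum 24 h mouse 4 8, serum 3 h mouse 1 4, serum 4 h mouse 1 2, and serum 1 h mouse 4, OA 3 h mouse 7, OA 4 h mouse 2, serum 18 h mouse 4 or OA 24 h mouse 3 1 each. For the late minus early difference, leaving out serum 18 h mouse 4 or the time of 1 h gave 1 each.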

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

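The count with array 38 at 1.5 h was chosen after the data were seen. In 66 groups of OA mice tested (the genes always given, except the saturated Hba-a1, and those called at a time), 3 held a mouse far from the others, and chance alone gives about 1 in 20. In OA 4 h mouse 3, Il1rn was at 9.97 against 8.82 to 8.92 in the 3 other mice, and Cd3e at 10.71 against 9.45 to 9.65. In OA 24 h mouse 6, Lcn2 was at 8.77 against 8.31 to 8.38.

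Array 38 is titled OA 3 h, and the authors' deposited ratios set it against serum of 1.5 h. Its profile correlated across clones with those of the OA mice at 1.5 h by 0.248 on average (-0.013 to 0.363) and with those of the 3 other OA mice at 3 h by 0.098 (-0.401 to 0.42), a difference of 0.15. Without the 1 of these that stands apart from most others, the mean for the 2 left was 0.348 (0.275 to 0.42), above that for 1.5 h. A wrong time in its title and a slip in the ratios cannot be told apart, because these ranges overlap and the order of the means turns on 1 mouse. No biological explanation was tested. Counted at 1.5 h, it left 687 clones changed between early and late OA mice, against 637.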

How the results depend on the processing

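Of 150 counts of calls under alternatives other than leaving out a mouse, 106 stayed within 1.5 times, and of 1347 values of named genes 1106 kept direction and call, 211 lost the call, 21 gained it and 1 reversed (Trim10 in OA mice, -0.12 without 24 h). Some alternatives were chosen after seeing the data, namely the first component score, leaving out the 7 mice, array 38 at 1.5 h, leaving out each time of late against early, the counts at its SE, array 38 on 1.5 h serum in the ratio table, OA-against-serum lists without the 7 mice and all list tests of late against early. The averaged comparison stayed at 0 clones under the 12 alternatives run for it (without the 7 mice it covers 5 times, since no serum mouse of 4 h remains). Changed clones between early and late OA mice numbered 562 to 852 under the alternatives set beforehand other than leaving out a mouse (637 as reported), with 594 of the 637 shared under median scaling (560 up, 292 down, against 337 and 300), 588 with the authors' quantile table (289 up, 355 down) and 519 with 1 array per mouse. With the first component score as a covariate there were 1357 (all 637 shared) and without the 7 mice 1363 (617 shared). Without 1.5 h there were 0, without 24 h 4 (3 shared), without 18 h 1274 (555 shared) and without 1 h 725 (505 shared), and in serum mice 0, 0, 1 and 1, while the late minus early difference gave 1 without 1 h (0 as reported). Fewer mice widen the SE, and in OA mice the reported changes at the SE without 1.5 h and without 24 h would give 0 and 35. The single calls of OA against serum, 1 at 1.5 h, 4 at 4 h and 1 at 24 h, and the 2 in serum late against early were less stable. Median scaling left 1 at 4 h and 0 in serum. Normexp gave 18 at 4 h, and 1 in the test over all times (0 as reported). The ratio table, with 3 h serum added back to array 38 although its ratios were made on 1.5 h serum, left 0 at 1.5 h, 2 at 4 h, 0 at 24 h and 0 in serum. With 1.5 h serum for that array all 8 calls were kept (1, 4, 1 and 2), so these losses come from the rebuild of 1 array. Without the dimmest 25% of clones there were 0 at 1.5 h, where Aqp11 was no longer tested in that smaller set. With 1 array per mouse there were 0 at 4 h, 0 at 24 h and 1 in serum, and with the array number as a covariate 2 at 4 h and 0 at 24 h. Fitting the compared groups alone, with fewer mice to estimate the spread, left 0 at 1.5 h, 0 at 4 h, 0 at 24 h and 0 in serum. The first component score gave 2 at 1.5 h, 2 at 4 h and 1 in the test over all times. Leaving out the 7 mice gave 4 at 1.5 h, 1 at 18 h (0 as reported), 0 at 24 h and 0 in serum, and it was not run for 4 h and the test over all times, where no serum mouse of 4 h would remain. Lists called for OA against serum were 1 as reported, 0 with an estimated correlation, 10 with median scaling, 3 without the 7 mice and 11 with both (0 and 0 with an estimated correlation), and for late against early 5 as reported, 0 with an estimated correlation and 0 without 24 h. The causes of the other differences were not tested. Over alternatives, the adjusted p ranged from 1.01e-07 to 0.835 for Aqp11 at 1.5 h, from 0.0188 to 0.782 for Dld, 0.0154 to 0.782 for Aldh9a1, 0.00466 to 0.782 for Ppp1r1b and 0.000507 to 0.782 for Wrnip1 at 4 h, from 0.0116 to 0.455 for Ccne1 at 24 h, and in serum mice from 0.0102 to 0.705 for Mpp1 and from 0.0123 to 0.808 for Ltf.

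Leaving out 1 mouse in turn gave 0 to 2 clones for the average, 0 to 2 at 1 h, 1 to 1 at 1.5 h, 0 to 4 at 3 h, 1 to 764 at 4 h (764 without serum mouse 4), 0 to 4 at 18 h and 0 to 34 at 24 h (34 without serum mouse 4). It gave 0 to 1 for the late minus early difference, 256 to 912 for late against early OA mice (256 without OA 1 h mouse 5), 0 to 6 for serum mice (6 without serum 24 h mouse 4) and 0 to 22 in the test over all times (22 without serum 4 h mouse 4). The lone serum mouse at 1.5 h cannot be left out. Where 1 serum mouse remained, it is assumed to vary like the other groups.

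Mouse numbers recur between times but do not pair the mice. Deviations of mice with the same number had a mean correlation of -0.003 over 67 pairs, against 0.004 over 253 pairs with other numbers. With a replicate block on mouse number, late against early gave 780 clones in OA mice (491 shared with the 637) and 0 in serum mice. OA and serum mice of the same time do not carry the same numbers, so no block was possible between them.

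Signal over background limits dim clones, since 41.8% to 57.88% of clone spots on an array were well above the empty spots. For late against early OA mice, 1 of 100 splits of single mice, the real one, gave 637 clones (highest other 392). Mice of 1 group are more alike, so chance differences among times stay open. For serum mice 12 of 35 splits gave at least the 2 clones found, with up to 9 in another, so chance cannot be excluded. For the average over times and for the late minus early difference, with 0 clones each, every split gives at least as many (100 of 100), so the splits decide nothing, with up to 1681 and 42 in another. At least 1 clone was called in 42 of the other splits for the average, in 41 for the difference and in 16 for serum mice. A few calls can thus arise from regrouping the mice, and the calls of OA against serum at single times were not tested by splits. Why 1 split gave 1681 clones was not tested.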

Other observations

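Tests of oleic acid alone, red cell RNA, weak hybridization and oleic acid as the reason for the mice apart were chosen after the results were seen. The 2 serum mice at 24 h lay far apart in myeloid genes, chosen here after their values were seen. In serum 24 h mouse 1, Il1b was at 13.35, Il1rn at 12.12, S100a8 at 13.14, S100a9 at 13.21, Slpi at 12.38 and Lcn2 at 11.06, and in serum 24 h mouse 4 they were at 10.11, 8.26, 9.51, 9.41, 8.83 and 8.13. Mpp1 was at 10.63 and 10.69 in the same mice.

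Of the 637 clones that changed between early and late OA mice, 614 had the same sign in serum mice, where 2 clones passed. Oleic acid alone is argued against as the cause, since over these clones the changes in OA and serum mice correlated at 0.91, which 1 of the 35 splits of the 7 serum mice reached, the real one (highest other 0.634). These splits exchange single mice, whereas mice of 1 group are more alike, so chance differences among times stay open here too. A linear trend with the array number and the 7 mice that stand apart are argued against too: the median change of these clones was 1 times its size with the array number in the model and 0.98 times without those mice. Of the OA mice compared, only OA 18 h mouse 2 is among the 7. Batches of arrays were not tested, and the labels do not say that the array number is the order of hybridization. Arrays of OA mice were dimmer at 24 h than at 1.5 h, with median clone signals of 83 to 196 against 228 to 364. The shares of clone spots well above empty spots were 46.18% to 51.28% against 53.07% to 57.88%. At 1 h and 18 h the signals were 141 to 222 and 109 to 238. Serum arrays gave 159 to 344 at 1 h, 212 at 1.5 h, 203 to 312 at 18 h and 191 and 195 at 24 h. Whether weaker signal added to the changes was not tested. More red cell RNA cannot be told apart from other causes by a list of 20 erythroid genes, some also expressed in other blood cells, with Hba-a1 saturated throughout. At 24 h 19 of these genes lay above early in OA mice and 16 in serum mice. The lower share, 0.8, equalled the limit set for this cause but did not exceed it. At 18 h 13 lay above early in OA mice and 12 in serum mice. That lower share, 0.6, rests on too few genes to decide (list means of -0.372 to 0.234 in OA mice, within the early range of -0.702 to 0.238). A preparation of mononuclear cells would deplete red cells, but Hba-a1 was saturated on every array, so its RNA was present in every sample. The depletion is therefore no argument against red cell RNA. Changes common to both treatments, such as handling, anesthesia or time of day, stay open and were not tested.

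On the first principal component, with 36.2% of the variance, 7 mice scored 38.2 or more and the 30 others 6.7 or less: OA 3 h mouse 7, OA 4 h mice 2 and 3, serum 4 h mice 1 and 4, OA 18 h mouse 2 and serum 18 h mouse 1. The highest of the others were the remaining mice of 4 h, OA 4 h mice 5 and 6 (6.7 and 6). All the rest scored -7.8 or less, so every mouse of 4 h, OA or serum, lay above them. Oleic acid is argued against as the cause, since 3 of the 7 are serum mice. A fault of single hybridizations is argued against only for the 2 mice among them with 2 arrays, OA 18 h mouse 2 and serum 4 h mouse 4. Of these, 0 had 1 array apart and 1 not. The rest of the 7 have 1 array each, so such a fault stays open for them. Weak hybridization or poorer RNA may be a cause, since the median share of clones well above empty spots was 47.5% in the 7 and 53.5% in the others, and 1 other mouse lay below the median of the 7. The shares overlapped (41.8% to 49.2% and 46.3% to 57.9%), as did the median signals (89 to 203 and 97.5 to 364). OA 24 h mouse 6, with 49.57% and 46.58% on its 2 arrays, scored -8.5, and OA 1 h mouse 3, with 48.72%, scored -13. Weak signal alone thus did not set every mouse apart. A biological difference at 3 to 18 h common to both treatments stays open and was not tested.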
